A study of Arabidopsis thaliana with 6 samples.

How the data were processed

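Total RNA from unopened flower buds was hybridised, after biotin labelling, to Affymetrix ATH1 arrays, 1 array per sample. The labels place the 6 samples in 3 groups of 2, taken on days 3, 4 and 5 of drought. The deposited table holds 1 log2 value per probe set and array, made by the authors with RMA (background correction, quantile normalization and median polish) in the affy package, per the submitters' processing notes. Versions, and which arrays were normalized together, are not given in the sources used here. The values lay between 2.98 and 14.74, and the array medians between 7.41 and 7.46, as computed here. Quantile normalization gives every array nearly the same distribution, so a change shared by most transcripts cannot be seen in these values. The number of arrays limits the precision, and the median SE of a log2 change between 2 days was 0.11.

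Of 22810 probe sets, the 64 controls of the array maker were left out of the tests and 22746 were tested. Genes were named through the platform annotation. Of the tested probe sets 13513 carried the name of exactly 1 gene, 503 carried several and 8730 were not named here, and no gene was named from a probe set with several. Symbols are those of that annotation, 13436 of the 1-gene probe sets matched the RefSeq gene table of TAIR10.1, and genes without a symbol are given by locus. No coordinates are given because the build behind the array annotation is not given in the sources used here.

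All 6 arrays entered 1 linear model with the day as its only term, fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes without trend). The model had 3 residual degrees of freedom, and the prior added 8.01. Contrasts were day 4 against day 3, day 5 against day 4, day 5 against day 3 and day 4 against the mean of days 3 and 5, with a moderated F test over the 3 days. P-values are two-sided and were adjusted by Benjamini-Hochberg over all tested probe sets of a contrast, with a threshold of 0.05. On simulated data with 200 of 22746 probe sets changed between days 3 and 5, the model recovered 63% of changes of 0.5 and 100% of changes of 1 on the log2 scale, with 10 and 18 false calls. The simulated errors were independent between probe sets, and the data gave 6566 calls for that contrast. These rates therefore need not hold for the data.

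Before the data were examined, 29 gene lists with 577 members were fixed for this tissue and treatment. Of these members 78 had a probe set named with that gene alone and are called measured below, and 9 were left out because symbol and locus disagreed. The other members had no such probe set here, and some may lie among the 8730 probe sets not named. The probe set with the highest mean stood for a gene with several. The 14 lists with at least 3 measured members were tested with camera at a preset correlation of 0.01 and adjusted over the lists of a contrast. None of the 9 camera calls held with an estimated correlation. A list of ribosomal protein genes could not be made without gene descriptions. Named genes were also chosen by a rule fixed in advance. It took, per contrast, the 8 largest rises and 8 largest falls among the calls with a name of exactly 1 gene and no overlap between the samples of the days, 5 in each direction for day 4 against the other days, and up to 4 members with the smallest p of each list for day 5 against day 3. Further list members named for the single steps and for day 4 against the other days, and the genes named in the closing section, were chosen after their values were seen and run under the same alternatives.

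Alternatives planned in advance were another prior, centring on the array median, repeated quantile normalization, leaving out dim or cross-hybridising probe sets, the replicate number as a block, leaving out each array, a fit of only the days compared, a 2-fold minimum and, for lists, an estimated correlation, fry and the mean of a gene's probe sets. Scaling to the mean of 24 poly-A control probe sets and cyclic loess were added after the data had been seen. The labels do not say whether control RNA was added in equal amounts to each sample.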

Results

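Transcript levels were measured in unopened flower buds of Arabidopsis thaliana plants with a mutated DREB1A gene, in the Col-0 background, over 3 days of soil drought. DREB1A encodes a transcription factor that binds a drought- and cold-responsive promoter element. Water was withheld from plants that had grown for 24 days and had a main stem of about 1 cm. Soil moisture reached about 35% of capacity some 80 hours later, which the labels call day 3, and was then held by watering. Buds were taken on days 3, 4 and 5, at plant ages of 28, 29 and 30 days. Each day gave 2 samples, and each of the 6 samples was hybridised to its own ATH1 array. The number of arrays limits the precision of every value. Wild-type and well-watered buds were not analysed here, so each comparison is between days of drought within the mutant. Plant age rose together with the day of drought, so age and length of drought cannot be told apart in any comparison. Nothing in the labels says that replicates came from separate plants, and the p-values therefore measure the spread between these samples, which may be technical. Replicate arrays of a day differed by a median of 0.10 to 0.13 on the log2 scale, while arrays of days 3 and 5 differed by a median of 0.20 to 0.22.

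No probe set used here carried the name of DREB1A, DREB1B or DREB1C, so the levels of these genes were not analysed here and the genotype rests on the labels. Among the other genes, 7045 of 22746 probe sets differed among the 3 days in the moderated F test of limma (adjusted p under 0.05). Without day 5 replicate 1 that count was 4681, and without day 5 replicate 2 it was 3842.

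The step from day 3 to day 4 asks what changed on the day after soil moisture had reached its low level. GI (AT1G22770), a gene of the circadian clock and of photoperiodic flowering, rose 5.58-fold (log2 change 2.48, SE 0.10, adjusted p = 5.18e-07 in limma, n = 2 per day). AT2G37870, of the lipid-transfer protein family, rose 8.00-fold, from 6.80 ± 0.32 to 9.80 ± 0.46 on the log2 scale (SD, n = 2). A cytochrome P450 gene, CYP71B31 (AT3G53300), rose by 2.41 (SE 0.26), and AT4G33550, a further gene of the lipid-transfer protein family, by 2.20 (SE 0.21). The linker histone gene HIS1-3 (AT2G18050), known to be induced by drought, rose by 1.74 (SE 0.23, adjusted p = 0.00237). Its call ended with a prior variance that follows the mean level (adjusted p = 0.0581). AT1G80130, AT5G52390 and AT3G51750 rose by 2.11, 2.00 and 1.66.

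Among the calls named with exactly 1 gene and without overlap of samples, the largest falls of that step were those of AT2G45180 and AT5G44020. AT2G45180, which belongs to the lipid-transfer protein family, dropped by 2.33 (SE 0.18, limma adjusted p = 9.37e-05). AT5G44020, an acid phosphatase family gene, dropped by 2.20 (SE 0.14). AT2G25510 fell by 1.84, AT2G30930 fell by 1.78, AT4G21870 fell by 1.69 and the calmodulin-like gene AT2G41090 fell by 1.68. The aluminium-induced protein genes AT3G15450 and AT4G27450 fell by 1.44 and 1.34.

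Of the fixed gene lists, that of DREB1 targets was shifted upward from day 3 to day 4 (camera adjusted p = 0.0163, and adjusted p = 0.505 with an estimated correlation). Its mean log2 change was 0.46 and its median 0.34, and whether DREB1 proteins drove the change was not tested. The call also ended without day 3 replicate 2 (adjusted p = 0.0599). Of its 5 measured members, 2 rose, the dehydrin gene LTI30 (AT3G50970) by 1.09 and the cold-regulated gene COR15A (AT2G42540) by 0.62, and 3 rose when adjusted over the list alone. Both measured genes of the abscisic acid and dehydration list rose, LEA4-5 (AT5G06760) by 0.99 (adjusted p = 0.0402) and LEA18 (AT2G35300) by 0.81 (adjusted p = 0.0369), and both rose when adjusted over the list alone. These 2 encode late embryogenesis abundant (LEA) proteins, which protect cells during water loss. The calls of LTI30 and LEA4-5 ended without day 3 replicate 1 (adjusted p = 0.115 and 0.286), day 3 replicate 2 (adjusted p = 0.0652 and 0.0916) or day 4 replicate 2 (adjusted p = 0.0515 and 0.229). That of COR15A ended without day 3 replicate 1 (adjusted p = 0.111), that of LEA18 without any 1 of the 4 arrays of the 2 days (adjusted p from 0.0670 to 0.189), and that of LEA4-5 also with a prior variance that follows the mean level (adjusted p = 0.249).

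Besides GI, 5 members of other lists passed the test for that step, and each call ended without at least 1 of the arrays. The carpel gene ALC rose by 0.61, the pollen receptor kinase gene ANX2 by 0.54 and the expansin gene EXPB3 by 0.50, while the organ growth gene JAG fell by 0.45 and the auxin-conjugating enzyme gene GH3.3 fell by 0.55. ANX2, EXPB3 and JAG did not pass without any 1 of the 4 arrays of the 2 days (adjusted p from 0.0514 to 0.192, from 0.0658 to 0.149 and from 0.0677 to 0.201). JAG did not pass without either day 5 array (adjusted p = 0.0535), with a prior that follows the mean level (adjusted p = 0.0636) or scaled to the poly-A controls (adjusted p = 0.0943). ALC and GH3.3 did not pass without day 3 replicate 2 (adjusted p = 0.171 and 0.181) or day 4 replicate 2 (adjusted p = 0.135 and 0.151), and GH3.3 without day 3 replicate 1 (adjusted p = 0.0716).

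Between days 3 and 4, 564 probe sets rose and 561 fell (limma, adjusted p under 0.05). The total of 1125 was 227 without day 3 replicate 1, 404 without day 3 replicate 2 and 392 without day 4 replicate 2. Rises made up 50.1% of these calls, against 68.0% when the arrays were scaled to the array maker's poly-A controls.

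**Figure D1:**
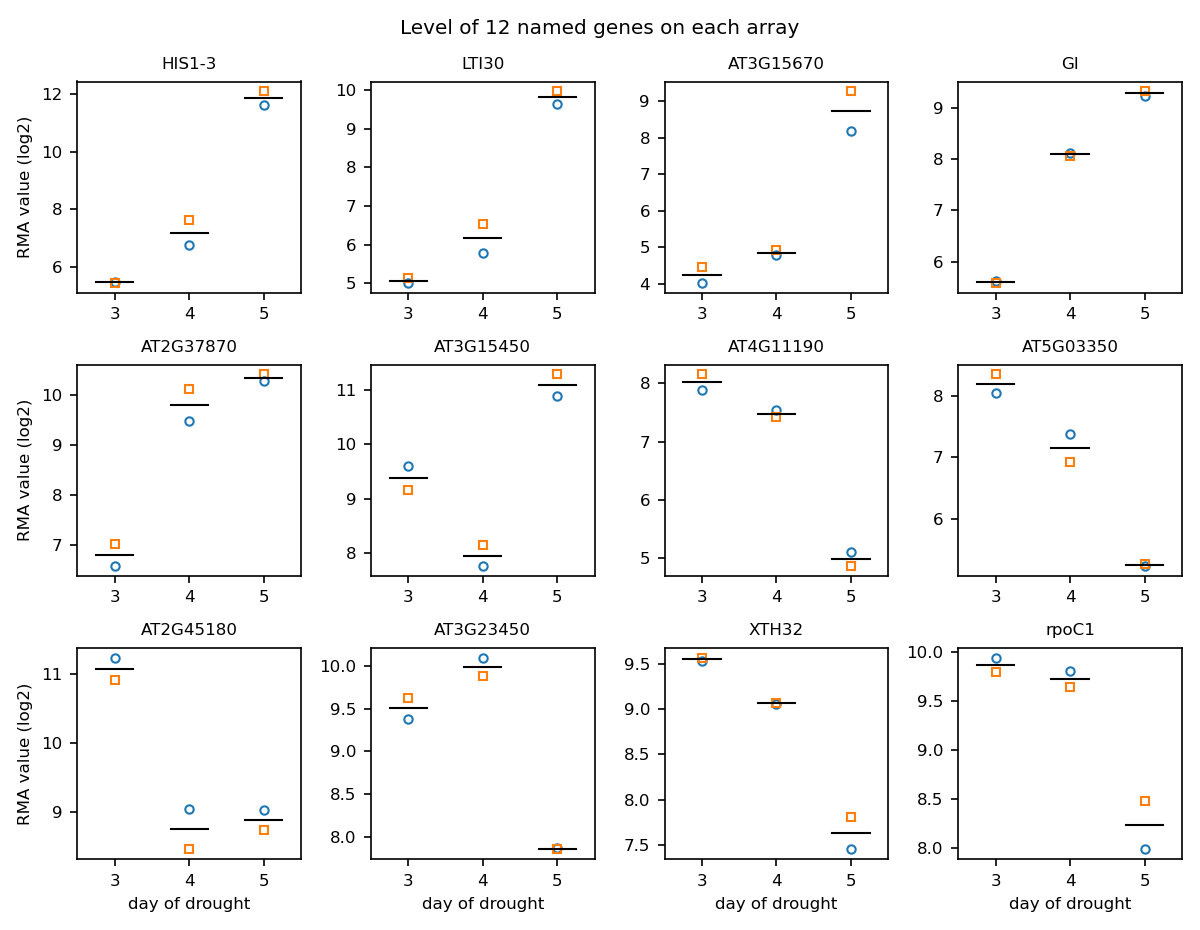
RMA level (log2, vertical axes that do not start at 0) of 12 named genes on each of the 6 arrays against the day of drought, with circles for replicate 1, squares for replicate 2 and a line at the mean of the 2. HIS1-3 stood at a mean of 5.45 on day 3 and 11.87 on day 5, GI rose at each step, and AT3G15450 was lowest on day 4.

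The step from day 4 to day 5 asks what changed with a further day at the same soil moisture. HIS1-3 rose 25.7-fold (log2 change 4.69, SE 0.23, adjusted p = 2.1e-06 in limma, n = 2 per day). LTI30 rose 12.5-fold (SE 0.20 on the log2 scale, adjusted p = 2.84e-06) and the LEA family gene AT3G15670 rose by 3.89 (SE 0.27), to 8.73 ± 0.77 (SD, n = 2). AT3G17520, of the same family, rose by 3.67 (SE 0.36), but by 4.49 without day 5 replicate 1 and 2.86 without day 5 replicate 2, as its day 5 level was 7.79 ± 1.16 (SD, n = 2). Its day 4 level of 4.12, and that of AT1G22890 (4.34), lay near the mean of 3.73 of the absent trp controls. AT2G21820, AT1G22890 and AT5G66780 rose by 3.64, 3.42 and 2.92. AT3G15450, which had fallen on day 4, rose by 3.15 (SE 0.18), to 11.09 ± 0.28 (SD, n = 2).

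The dirigent protein family gene AT4G11190 dropped by 2.49 from day 4 to day 5 (SE 0.13, adjusted p = 2.1e-06), from 7.48 ± 0.09 to 4.99 ± 0.17 (SD, n = 2). The glycine-rich protein genes AT3G23450 and AT5G46730 fell by 2.13 and 1.49, and the legume lectin family gene AT5G03350 fell by 1.90. AT3G14395 fell by 1.83. BCAT4, an aminotransferase gene of methionine-derived glucosinolate synthesis, fell by 1.69 (SE 0.13), and XTH32, of the family that remodels wall xyloglucan, fell by 1.43. The gene rpoC1, which the plastid genome carries and which encodes a subunit of the plastid RNA polymerase, fell by 1.49 (SE 0.15).

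The camera test called 4 lists for that step. All 3 measured genes of the gibberellin list rose, also when adjusted over the list alone. These were the receptor genes GID1A (AT3G05120), GID1B (AT3G63010) and GID1C (AT5G27320), up by 0.81, 1.26 and 0.73 (camera adjusted p = 0.000474, and adjusted p = 0.201 with an estimated correlation). Scaled to the poly-A controls, GID1A and GID1C did not pass (adjusted p = 0.0853 and 0.257). Of the 5 DREB1 targets 3 rose, LTI30, the zinc finger gene STZ (AT1G27730, also called ZAT10) by 0.80 and COR15A by 0.37, although scaled to the poly-A controls COR15A turned to -0.18 and STZ, at 0.25, did not pass. Adjusted over the list alone 4 rose, and the list's mean change of 0.98 stood against a median of 0.37. That list's camera adjusted p was 0.00559, its adjusted p was 0.201 with an estimated correlation, and its call ended when the dimmest 30% of probe sets were left out (adjusted p = 0.0747). COR15A did not pass without day 4 replicate 2, day 5 replicate 1 or day 5 replicate 2 (adjusted p = 0.150, 0.0773 and 0.178).

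Of 6 sugar starvation genes 4 rose from day 4 to day 5, also when adjusted over the list alone (camera adjusted p = 0.00939, adjusted p = 0.201 with an estimated correlation). They were MCCA up by 0.44, IVD by 0.41, AKINBETA1 by 0.40 and ATL8 by 0.32, but scaled to the poly-A controls they turned to -0.11, -0.14, -0.15 and -0.23 and the list's mean turned from 0.30 to -0.25. Without day 5 replicate 2 none of the 4 passed (adjusted p = 0.104, 0.113, 0.132 and 0.198, in that order). AKINBETA1 and ATL8 did not pass without day 5 replicate 1 (adjusted p = 0.0941 and 0.128), IVD and ATL8 without day 4 replicate 1 (adjusted p = 0.0715 and 0.187), AKINBETA1 without day 4 replicate 2 (adjusted p = 0.122), and ATL8 without either day 3 array (adjusted p = 0.0650) or with arrays centred on their median (adjusted p = 0.0601).

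The 3 measured cell cycle genes fell from day 4 to day 5, also when adjusted over the list alone (camera adjusted p = 0.0102, adjusted p = 0.201 with an estimated correlation). MCM7, labelled PRL here (AT4G02060), a replication helicase subunit, dropped by 0.72, and the Aurora kinase genes AUR2 and AUR1 stood at log2 changes of -0.52 and -0.49. Scaled to the poly-A controls the mean of the list moved from -0.58 to -1.13 and its adjusted p was 0.0802, and without day 5 replicate 2 that of AUR2 was 0.0563.

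Both LEA genes rose again from day 4 to day 5, LEA4-5 by 1.87 and LEA18 by 2.46. WES1 (AT4G27260, also called GH3.5), an auxin-conjugating enzyme gene, rose by 1.93 (SE 0.14, adjusted p = 1.71e-05). The expansin gene EXPA15 (AT2G03090) dropped by 1.19 (SE 0.11). The jasmonate pathway genes moved apart, with OPCL1 up by 0.71 (adjusted p = 0.315 scaled to the poly-A controls) and JMT, a jasmonate methyltransferase gene, down (log2 change -0.72).

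Between days 4 and 5, 2395 probe sets rose and 3048 fell (limma, adjusted p under 0.05). The total of 5443 was 3398 without day 5 replicate 1 and 2506 without day 5 replicate 2. On the same arrays the median of 24 poly-A control probe sets was 0.50 higher on day 5 than on day 4, and the control probe set for 25S ribosomal RNA was 0.93 higher. Among calls of at least 2-fold, 276 rose and 86 fell. Rises made up 44.0% of all calls, 55.2% after cyclic loess and 1.97% of 19570 calls after scaling to the poly-A controls. That scaling moved the median change of all probe sets by far more than any other setting, to -0.60 for day 5 against day 4, -0.50 for day 5 against day 3 and 0.34 for day 4 against the mean of the other days, and every change given here is relative to the level of the array as a whole.

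The comparison of day 5 with day 3 spans both steps. HIS1-3 rose 85.7-fold (log2 change 6.42, SE 0.23, adjusted p = 9.07e-08 in limma), from 5.45 ± 0.03 to 11.87 ± 0.35 (SD, n = 2). LTI30 rose 26.6-fold. AT2G21820, AT5G66780 and the LEA family genes AT3G15670 and AT3G17520 rose by 5.02, 4.57, 4.50 and 3.71, from day 3 levels of 4.64, 4.04, 4.23 and 4.08 that lay below the lower quartile of the arrays, toward the absent trp controls, and the rise of AT3G17520 was 4.53 without day 5 replicate 1 and 2.89 without day 5 replicate 2. GI rose 12.7-fold (SE 0.10 on the log2 scale, adjusted p = 1.46e-08) and AT2G37870 11.7-fold (adjusted p = 9.61e-07). AT4G11190 dropped by 3.03 (SE 0.13, adjusted p = 2.29e-07), AT5G03350 dropped by 2.95, AT2G41090 dropped by 2.55 and AT2G45180 dropped by 2.20. AT5G44020, AT1G56680, AT1G62500 and XTH32 had log2 changes of -2.19, -2.14, -1.97 and -1.92.

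Of the 5 measured DREB1 targets 4 rose from day 3 to day 5, LTI30 by 4.73, COR15A by 1.00, STZ by 0.95 and COR47 by 0.66 (camera adjusted p = 0.00126, adjusted p = 0.268 with an estimated correlation). COR15B stood at a log2 change of -0.14 (adjusted p = 0.386), and the list's mean was 1.44 and its median 0.95. The rise of COR47 did not pass the test when scaled to the poly-A controls (adjusted p = 0.272). Both dehydration genes rose, LEA18 by 3.26 (SE 0.19) and LEA4-5 by 2.87 (SE 0.24). GI, the only listed evening clock gene with a probe set named here, rose as given above. All 3 gibberellin receptor genes rose, GID1B by 1.04, GID1C by 0.61 and GID1A by 0.43 (camera adjusted p = 0.00919, adjusted p = 0.308 with an estimated correlation), although GID1A turned to -0.06 and GID1C was not past the test (adjusted p = 0.453) when scaled to the poly-A controls. The call of GID1A ended without day 3 replicate 2 (adjusted p = 0.0849) and without day 5 replicate 2 (adjusted p = 0.0973), and that of GID1C without day 5 replicate 2 (adjusted p = 0.0501).

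All 3 measured cell cycle genes fell from day 3 to day 5, MCM7 (PRL) by 0.90 and the Aurora kinase genes AUR1 (AT4G32830) and AUR2 (AT2G25880) by 0.82 and 0.75 (camera adjusted p = 0.00316, adjusted p = 0.268 with an estimated correlation). Of 6 cell wall loosening genes, the expansin genes EXPA15 and EXPA4 fell by 0.95 and 0.68 and EXPA8 rose by 0.69, with EXPA16 at -0.19 (camera adjusted p = 0.43). EXPA8 did not pass the test when scaled to the poly-A controls (adjusted p = 0.211). Of 6 photosynthesis genes 2 fell, the photosystem subunit genes PSAN by 0.46 and PSAE-1 by 0.37, while PSBW and LHCB4.1 stood at 0.16 and 0.09 (camera adjusted p = 0.589, fry adjusted p = 0.0110 with a list mean of -0.11). The call of PSAE-1 ended without any 1 of the 4 arrays of the 2 days (adjusted p from 0.0621 to 0.108) and after cyclic loess (adjusted p = 0.0629).

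Of the flower lists, the sporocyte gene SPL fell by 0.51, and CLV3, JAG and UFO stood at 0.23, -0.14 and -0.04, in a list of 4 genes of floral identity and the meristem (camera adjusted p = 0.623). In the carpel and ovule list ALC rose by 0.77, with SPT at 0.20 and INO at -0.08 (camera adjusted p = 0.295), and scaled to the poly-A controls the rise of ALC did not pass (adjusted p = 0.107). Both measured genes of the tapetum list fell, the receptor kinase gene EMS1 by 0.49 and the transcription factor gene AMS by 0.54. Of 5 meiosis genes 1 fell, ATMND1 by 0.45, and 2 fell when adjusted over the list alone, while SDS, RCK and ZYP1b stood at -0.28, -0.23 and -0.31 (camera adjusted p = 0.155, and fry adjusted p = 0.0230, a test that does not set the list against other genes). Of 5 late pollen genes, AGL65 and ANX2 rose by 0.42 and 0.45 and ANX1 and AGL66 stood at 0.06 and 0.02 (camera adjusted p = 0.295), though AGL65 and ANX2 turned to -0.07 and -0.04 when scaled to the poly-A controls. The calls of SPL, AGL65 and AMS ended without day 3 replicate 1 (adjusted p = 0.0994, 0.116 and 0.0553) and without day 5 replicate 1 (adjusted p = 0.0566, 0.0747 and 0.147). Those of AMS and ANX2 ended without day 3 replicate 2 (adjusted p = 0.102 and 0.156), that of ANX2 without day 5 replicate 1 (adjusted p = 0.131), and those of AGL65 and ATMND1 without day 5 replicate 2 (adjusted p = 0.0621 and 0.0508).

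Of 6 sugar starvation genes 3 rose from day 3 to day 5, IVD and MCCA, of leucine breakdown, by 0.50 and 0.38 and the ubiquitin ligase gene ATL8 by 0.47, with ETFQO at 0.26 (camera adjusted p = 0.0216, adjusted p = 0.308 with an estimated correlation), but the list's mean turned from 0.31 to -0.17, and ATL8 and MCCA to -0.02 and -0.11, when scaled to the poly-A controls. With that scaling IVD did not pass the test (adjusted p = 0.938). The list's call ended without day 3 replicate 2 (adjusted p = 0.0683), the calls of ATL8 and MCCA without day 3 replicate 1 (adjusted p = 0.0501 and 0.132) and that of MCCA without day 5 replicate 2 (adjusted p = 0.147). Of 5 flavonoid and anthocyanin genes 2 rose, the dihydroflavonol reductase gene DFR (AT5G42800) by 1.07 and the anthocyanin glycosyltransferase gene UF3GT (AT5G54060) by 0.94, and 1 fell, the flavonol glycosyltransferase gene UGT78D1 by 0.57. AT5MAT stood at 0.32 and passed when adjusted over the list alone, which made 3 rises (camera adjusted p = 0.337).

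Of 6 auxin genes WES1 rose by 2.03 (SE 0.14, adjusted p = 3.76e-06) and GH3.3 fell by 0.70, with YUC6 and YUC4 at -0.18 and -0.16 (camera adjusted p = 0.978). The mean change of that list was 0.17 and its median -0.07. The jasmonate synthesis gene OPCL1 rose by 0.41 and JMT stood at -0.36, a fall when adjusted over the list alone. Of the 3 touch and wound genes the calmodulin-like gene CML38 rose by 0.30, with WRKY53 at 0.08 and PUB23 at 0.02 (camera adjusted p = 0.46). Of 2 defence genes GRX480 rose by 0.32 and PDF1.2 stood at -0.16. Of 3 senescence genes WRKY6 rose by 0.38, with SAG101 at -0.15 and SAG29 at 0.02 (camera adjusted p = 0.623). Scaled to the poly-A controls, OPCL1, CML38, GRX480 and WRKY6 turned to -0.08, -0.18, -0.16 and -0.10. The calls of CML38 and GRX480 ended without any 1 of the 4 arrays of the 2 days (adjusted p from 0.105 to 0.19 and from 0.0651 to 0.251), and also with a prior that follows the mean level (adjusted p = 0.0624 and 0.0941). The call of WRKY6 ended without replicate 1 of day 3 or of day 5 (adjusted p = 0.245 and 0.244) and with that prior (adjusted p = 0.0556), and that of OPCL1 without either day 3 array (adjusted p = 0.0814 and 0.199) or day 5 replicate 2 (adjusted p = 0.32).

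The remaining lists held few measured genes, and none of these passed the test between days 3 and 5. They were the ethylene regulator EIN3 at 0.15, the heat shock genes ATHSP22.0 at -0.12 and AT5G48570 at -0.05, the wax synthase gene WSD1 at -0.06, the secondary wall gene GUT2 at 0.06 and the reference gene PEX4 at -0.13 (adjusted p = 0.367). Counts adjusted over the list alone equalled those over all probe sets for day 5 against day 3, except in the meiosis, jasmonate and flavonoid lists. In the lists of DREB1 genes, morning clock genes, antioxidant enzymes, aquaporins and seed maturation genes, no member had a probe set named with it alone. These lists were not analysed here.

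**Figure D2:**
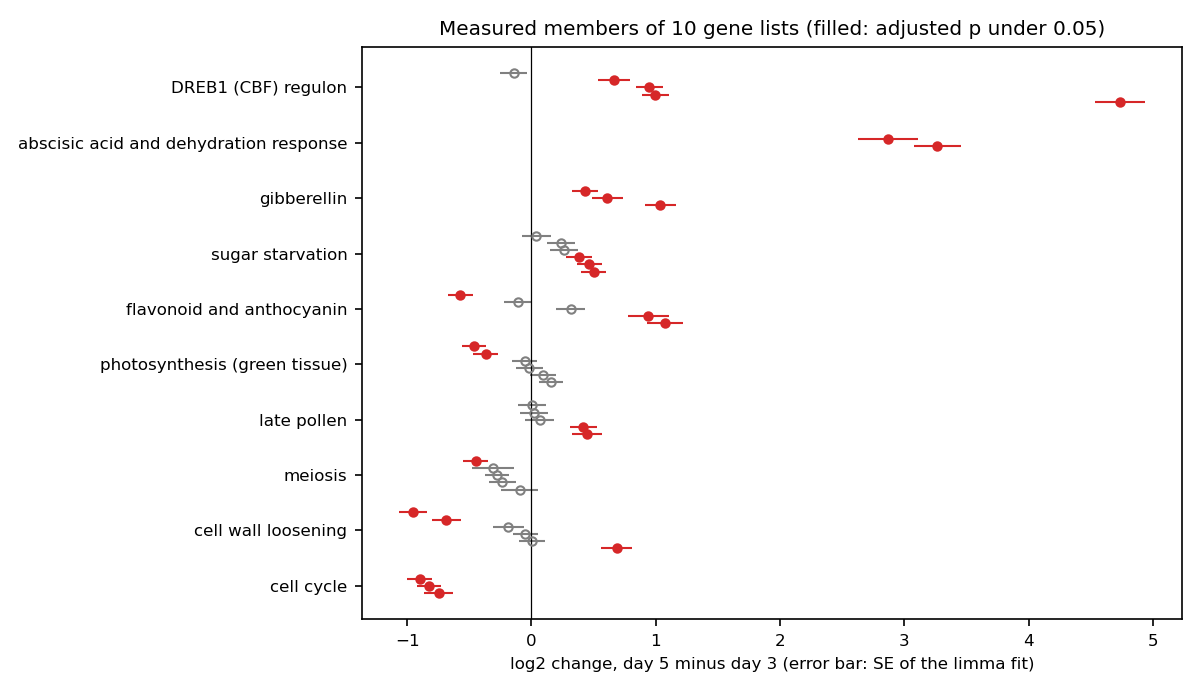
Change from day 3 to day 5 (horizontal axis, log2) of the measured members of 10 gene lists, with the SE of the limma fit as error bars. Filled red points have an adjusted p under 0.05, with LTI30 and the 2 dehydration genes farthest right at 4.73, 3.26 and 2.87, the 3 cell cycle genes between -0.90 and -0.75, and the sugar starvation genes at a mean of 0.31 that turned to -0.17 when scaled to the poly-A controls.

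From day 3 to day 5, 2994 probe sets rose and 3572 fell (limma, adjusted p under 0.05). The total of 6566 was 4362 without day 3 replicate 1, 4097 without day 3 replicate 2 and 3844 without day 5 replicate 2. The poly-A controls were higher on day 5 than on day 3 by a median of 0.46 and the 25S ribosomal RNA control by 1.11. Among calls of at least 2-fold, 456 rose and 290 fell. Rises made up 45.6% of all calls, against 53.1% after cyclic loess and 3.93% of 18174 calls when the arrays were scaled to the poly-A controls.

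**Figure D3:**
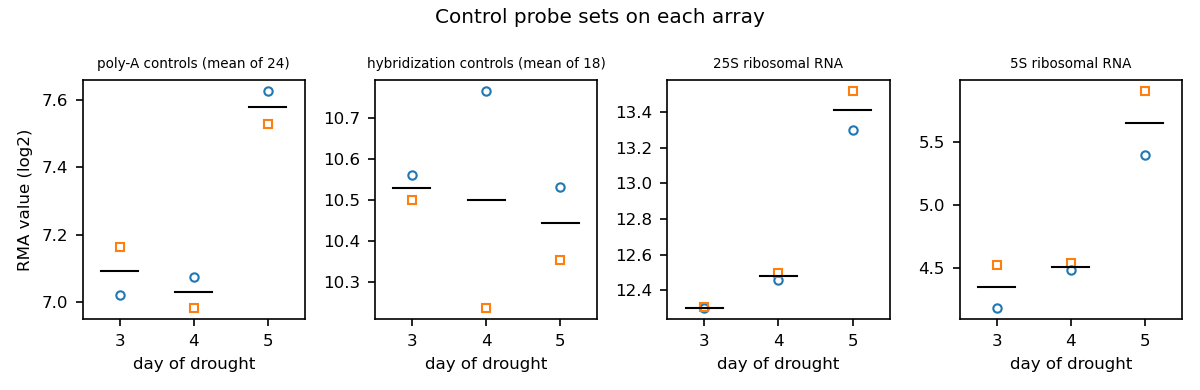
RMA level (log2, vertical axes that do not start at 0) of control probe sets on each of the 6 arrays against the day of drought, with circles for replicate 1, squares for replicate 2 and a line at the mean of the 2. The poly-A mean was 7.09 on day 3, 7.03 on day 4 and 7.58 on day 5, the hybridization mean was 10.53, 10.50 and 10.44, and the 25S ribosomal RNA control was 12.30, 12.48 and 13.41.

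A contrast of day 4 with the mean of days 3 and 5 asked which genes stood apart on the middle day. AT3G15450 and AT4G27450, the aluminium-induced protein genes, were lower on day 4 by a log2 difference of -2.29 (SE 0.15, adjusted p = 6.92e-05 in limma) and -1.93. AT1G22890, the ethylene response factor family gene AT5G61590 and the glycine-rich protein gene AT2G05540 stood at -1.89, -1.67 and -1.55. The glycine-rich protein gene AT3G23450 was higher on day 4 by 1.31 (SE 0.10, adjusted p = 0.000199), AT5G52390 by 1.29 and AT5G46730 by 0.98. AT5G20390 and AT3G17110 were higher by 0.86 and 0.83. The call of AT5G20390 ended without day 3 replicate 2, day 4 replicate 1 or day 4 replicate 2 (adjusted p = 0.0504, 0.0639 and 0.142) and that of AT3G17110 without day 4 replicate 2 (adjusted p = 0.0897). The gibberellin receptor genes GID1A, GID1B and GID1C were lower on day 4, at -0.60, -0.75 and -0.43, all 3 also when adjusted over the list alone. GID1C did not pass scaled to the poly-A controls (adjusted p = 0.403), with arrays centred on their median (adjusted p = 0.0585) or without any 1 array except day 5 replicate 1 (adjusted p from 0.0831 to 0.177).

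On day 4, 770 probe sets were higher and 794 lower than the mean of days 3 and 5 (limma, adjusted p under 0.05). The total of 1564 was 506 without day 3 replicate 1, 852 without day 3 replicate 2, 807 and 471 without day 4 replicates 1 and 2, and 962 and 710 without day 5 replicates 1 and 2, and it was 2482 with a prior variance that follows the mean level. Among calls of at least 2-fold, 8 were higher and 57 lower. Higher calls made up 49.2% of the total, against 37.7% after cyclic loess and 98.4% of 15061 calls when scaled to the poly-A controls.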

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

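The tests of the control probe sets and of the first step of GI were chosen after those results had been seen, and the tests of the trend with signal, of single arrays and of GI over both steps before. The poly-A and 25S ribosomal RNA control probe sets, which enter no comparison between genes, stood on average above the absent trp controls and differed by day. The 24 poly-A controls were higher on day 5 than on day 3 by a median of 0.46 on the log2 scale, and 24 of the 24 lay higher. These probe sets read the same few control RNAs (dap, lys, phe and thr), so they are not 24 independent controls. The 25S ribosomal RNA control was higher by 1.11.

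The 18 bio and cre hybridization controls changed by a median of -0.0663, which does not decide on a brighter hybridization or scan of the day 5 arrays, since quantile normalization removes brightness shared by an array. Degraded RNA would widen the gap between 3 prime and 5 prime control probe sets, and the mean change of that gap over 6 control pairs was 0.0167, which argues against it. These pairs cover only actin, GAPDH and ubiquitin, each with a further pair of older probe sets. A smaller share of messenger RNA in the day 5 samples may raise both kinds of control, with ribosomal RNA up by 1.11, but so may a separate labelling of that day. These cannot be told apart, since the amounts of control RNA and the labelling batches are not in the labels and each day may be a batch of its own. A change in the RNA makeup of the buds between the days stays open and untested.

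A further pattern was the larger number of calls from day 4 to day 5 (5443) than from day 3 to day 4 (1125). A trend of the change with the signal level, left by the normalization, would be removed by cyclic loess, and 5258 probe sets were still called, which argues against it as the whole cause. No 1 array accounts for it, as the ratio of the counts was 4.84 with all arrays and at least 2.65 without any 1 of them. The handling of day 5 and the day itself cannot be told apart, because the poly-A controls differed between days 4 and 5 by a median of 0.50 and each day may be a batch of its own. A response to longer drought, or the greater age of the plants, remains an open, untested explanation.

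GI was higher on each successive day. If buds were harvested at later clock hours on later days, evening-phased genes should rise against dawn-phased ones. From day 3 to day 5, COR27 and AT4G33980 (evening) rose by 1.54 and 1.77. AT1G69570 and AT5G52660 (dawn) rose by 0.34 and 0.52 (limma adjusted p = 0.0429 and 0.00569), and both calls ended without at least 1 array. The difference was 1.23 (SE 0.12), so a later hour is a candidate explanation for part of the rise, although neither dawn gene fell. That SE covers only the spread between arrays for these 4 genes. From day 3 to day 4, where GI rose by 2.48, the evening minus dawn difference was 0.11 (SE 0.12), so these 4 genes gave no sign of a later hour at the first step. This does not decide the question, since the daily rhythm of GI may differ from theirs in size and phase and was not measured here. From day 4 to day 5, where GI rose by 1.19, the difference was 1.11 (SE 0.12). The hour of harvest is not in the labels, and a response of these genes to drought or to plant age stays open and untested.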

How the results depend on the processing

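Of 221 results for named genes and 42 for gene lists, 39 changed direction with a call under at least 1 of the 2 settings, all when the arrays were scaled to the poly-A controls, a setting chosen after seeing the data, as was cyclic loess. With a call under neither setting, 7 named genes (CLV3, SPT, ETFQO, AT5MAT, ATG8G, ATG8D and ndhA) and 13 list means turned under that scaling, and 12 named genes and 8 list means under others. No called result changed direction under the other settings, and without 1 array 58 of the named-gene results and 2 of the list results lost their call at least once, where fewer samples enter the fit. Scaled to the poly-A controls, which shifts all probe sets at once, the changes from day 3 to day 5 became -0.33 for PSBW, -0.40 for LHCB4.1, -0.0709 for AGL65, -0.0399 for ANX2, -0.42 for ANX1, -0.46 for AGL66, -0.0788 for OPCL1, -0.0563 for GID1A, -0.33 for EIN3, -0.18 for CML38, -0.41 for WRKY53, -0.47 for PUB23, -0.16 for GRX480, -0.0205 for ATL8, -0.11 for MCCA, -0.43 for GUT2, -0.10 for WRKY6, -0.14 for AT1G69570, -0.0456 for SWEET1, -0.32 for ATG3 and -0.47 for SAG29. From day 4 to day 5 they became -0.18 for COR15A, -0.15 for AKINBETA1, -0.23 for ATL8, -0.14 for IVD, -0.11 for MCCA, -0.20 for ATG3, -0.13 for ATG8C, -0.21 for ATG8D, -0.0959 for atpH, -0.0722 for atpI, -0.21 for petB, -0.0752 for psbA, -0.11 for psbN, -0.44 for ndhC, -0.53 for ndhD and -0.35 for ndhI. The mean of the sugar starvation list became -0.25 for day 5 against day 4 and -0.17 for day 5 against day 3. That scaling called 19570 probe sets for day 5 against day 4, 18174 for day 5 against day 3, 15061 for day 4 against the other days and 19922 over the 3 days, and 2 lists for day 5 against day 4.

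With a 2-fold minimum, 93 probe sets were called for day 4 against day 3, 362 for day 5 against day 4, 746 for day 5 against day 3, 65 for day 4 against the other days and 821 over the 3 days, a stricter rule by construction. A prior that follows the mean level called 2482 for day 4 against the other days, and the cause was not tested. Leaving out 1 array gave 227 to 1033 calls for day 4 against day 3, 2506 to 4822 for day 5 against day 4, 3844 to 7034 for day 5 against day 3, 471 to 962 for day 4 against the other days and 3842 to 7121 over the 3 days. The lone array left of a day is assumed to vary like the other days. Lists called for day 4 against day 3 were 0 to 1 without 1 array. With an estimated correlation 0 lists were called in each comparison, and at an unadjusted p under 0.05 the DREB1 targets passed in all 3 (camera p = 0.0453, 0.0418 and 0.0281), the gibberellin list for day 5 against day 4 (p = 0.0442) and the cell cycle list for day 5 against day 3 (p = 0.0383). Fry, which does not set a list against other genes, called 3 lists for day 4 against day 3, 5 for day 5 against day 4 and 6 for day 5 against day 3. Those it added were all lower, photosynthesis and the cell cycle for day 4 against day 3 (adjusted p = 0.0131 each), meiosis for day 5 against day 4 (adjusted p = 0.0484), and meiosis and photosynthesis for day 5 against day 3 (adjusted p = 0.0230 and 0.0110). Fitted without day 5, day 4 against day 3 gave 946 calls, and comparisons with day 5 cannot be made without it.

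Replicate numbers are shared by the days, but the labels do not say what they mark. Differences between replicates 1 and 2 correlated across probe sets at 0.06, -0.00 and 0.10 between days. With 1 such difference per day, these values do not decide whether equal numbers mark shared plants or handling. With the replicate number as a block, 1310, 5614 and 6718 probe sets were called for day 4 against day 3, day 5 against day 4 and day 5 against day 3. Without the block these counts were 1125, 5443 and 6566. Probe sets near the lower end of the signal range have changes that background compresses, among them those of AT2G21820, AT5G66780, AT3G15670, AT3G17520, AT1G22890, CLV3, SDS, CML38, ndhF and rps14.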

Other observations

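The gene groups in this part were chosen after the probe names or some of the values had been seen. Genes of the plastid genome showed little change from day 3 to day 4, when none of 69 measured genes rose and 1, ndhK, fell by 0.55 (limma, adjusted p = 0.0127, but 0.131 without day 3 replicate 1, 0.0710 without day 4 replicate 2 and 0.0506 when scaled to the poly-A controls), and changed in both directions from day 4 to day 5. Then 19 rose and 13 fell, although scaled to the poly-A controls petB, psbN, atpH, psbA and atpI of the 19 turned to lower, and ndhH, ndhJ, ndhK, petD and petG did not pass (adjusted p = 0.496, 0.219, 0.154, 0.0587 and 0.0613). From day 3 to day 4 the share called was 1.4% of the plastid genes, against 4.9% of all tested probe sets. The 32 calls from day 4 to day 5 were 46.4% of the plastid genes, against 23.9% of all tested probe sets. With the dimmest 30% of probe sets left out, 5625 of the other 15922 were called for that step, a larger share than 23.9%. Of 10 genes for the plastid NDH complex 6 rose and none fell, ndhG by 2.46, ndhF by 2.45 and ndhE by 2.19 among them. On day 4 these 3 genes stood at only 6.30, 4.62 and 5.97, and ndhF lay below the lower quartile of the arrays. Scaled to the poly-A controls, only ndhG, ndhF and ndhE passed as higher. With that scaling ndhA, ndhC, ndhD and ndhI turned to -0.19, -0.44, -0.53 and -0.35, and the last 3 passed as lower. Among genes for photosystems and the cytochrome complex 9 of 26 rose and 4 fell, with psbT and psaC up by 2.03 each and psbC down (log2 change -0.84). Day 4 levels were 5.66 for psbT, 5.57 for psaC and 10.07 for psbC. Of 4 genes of the plastid RNA polymerase 2 fell, rpoC1 by 1.49 and rpoC2 by 0.59, from day 4 levels of 9.73 and 8.85. Thus ndhG, ndhF, ndhE, psbT and psaC began below the array medians, and psbC, rpoC1 and rpoC2 above them. Every called rise of a plastid gene of over 2-fold began below the array medians. Every called fall except that of rps16, at 7.37, began above them. Of the smaller called rises, those of atpH, ndhJ, ndhK, petB and psbA began above them, at 9.28, 9.13, 8.50, 12.24 and 9.30 on day 4. Direction thus went largely with the signal level among these calls, although no test of this was run. On the same arrays the 25S and 5S ribosomal RNA controls were 0.93 and 1.14 higher on day 5 than on day 4. A change in plastid transcript levels therefore cannot be told apart from one in RNA makeup or labelling. From day 3 to day 5, 15 of the 69 plastid genes rose and 11 fell, or 37.7%, against 28.9% of all tested probe sets. With the dimmest 30% of probe sets left out, 6636 of the other 15922 were called, a larger share than that of the plastid genes. Over that span 4 of the 10 NDH genes rose. There ndhJ and ndhK, at 0.28 and 0.21, did not pass (limma adjusted p = 0.121 and 0.162).

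For day 5 against day 4, 9 of the 19 plastid rises and 7 of the 13 falls lost their call without at least 1 array. Without day 5 replicate 2 none of petB, psbN, atpH, psbA and atpI passed (adjusted p = 0.184, 0.315, 0.141, 0.0566 and 0.242). Without day 4 replicate 2 petB, psbN, atpH and atpI did not (adjusted p = 0.169, 0.200, 0.176 and 0.223), without day 5 replicate 1 petB and atpH did not (adjusted p = 0.108 and 0.0821), and without either day 3 array petB, psbN and atpI did not (adjusted p = 0.0516, 0.0586 and 0.0554). The rises of petD, petN, psbB and rps14 (1.14, 1.26, 1.37 and 1.24) were 1.84, 1.88, 1.97 and 1.88 without day 5 replicate 1 and 0.44, 0.64, 0.76 and 0.59 without day 5 replicate 2, where petD and rps14 did not pass (adjusted p = 0.0545 and 0.0579). None of these 4 passed without day 4 replicate 2 (adjusted p = 0.0974, 0.0627, 0.0506 and 0.105) or with a prior that follows the mean level (adjusted p = 0.181, 0.132, 0.110 and 0.128), and petD did not without day 4 replicate 1 (adjusted p = 0.0831). Of the falls, none of atpA, petA, psaI, psbK, rbcL, rpl16 and rps16 passed without day 4 replicate 1 (adjusted p = 0.248, 0.0651, 0.121, 0.0783, 0.0504, 0.291 and 0.102) or day 5 replicate 1 (adjusted p = 0.125, 0.0582, 0.136, 0.208, 0.117, 0.234 and 0.277). Without day 5 replicate 2 atpA, petA, psaI, psbK and rpl16 did not pass (adjusted p = 0.169, 0.0536, 0.0619, 0.0706 and 0.0773), without day 4 replicate 2 psbK and rps16 did not (adjusted p = 0.131 and 0.108), and without either day 3 array rpl16 did not (adjusted p = 0.0679). After cyclic loess atpA, psaI, psbK, rpl16 and rps16 did not pass (adjusted p = 0.114, 0.0596, 0.146, 0.111 and 0.0528), nor atpA, psbK and rpl16 with quantile normalization repeated (adjusted p = 0.0786, 0.0738 and 0.0812).

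Symbols sharing a stem gave 30 families of at least 8 genes. The autophagy genes (ATG) stood out from day 4 to day 5, when 7 of 8 rose and none fell, ATG8E by 1.31, ATG8F by 0.92 and ATG8B by 0.67, although scaled to the poly-A controls only ATG8E and ATG8F passed, ATG3, ATG8C, ATG8D and ATG8G turned to lower and the mean of the family moved from 0.62 to 0.0684 (camera adjusted p over 30 families = 2.35e-06, adjusted p = 0.554 with an estimated correlation). The calls of ATG3, ATG8C and ATG8D also ended without day 5 replicate 1 (adjusted p = 0.166, 0.0965 and 0.0663) or day 5 replicate 2 (adjusted p = 0.125, 0.0529 and 0.239), those of ATG8C and ATG8D without day 4 replicate 2 (adjusted p = 0.0712 and 0.142), those of ATG3 and ATG8D without day 4 replicate 1 (adjusted p = 0.186 and 0.0542) or either day 3 array (adjusted p = 0.0534 and 0.0560), and that of ATG3 with arrays centred on their median (adjusted p = 0.0501). These genes encode ATG8 proteins of the autophagosome membrane and the enzyme ATG3 that acts on them. From day 3 to day 5, 6 of them rose (camera adjusted p = 0.000246, adjusted p = 0.78 with an estimated correlation), but scaled to the poly-A controls the mean moved from 0.55 to 0.0597, ATG3 and ATG8D turned to -0.32 and -0.19, and of the 6 only ATG8F passed, with ATG8B, ATG8C, ATG8E, ATG8G and ATG8H at adjusted p = 0.125, 0.495, 0.423, 0.916 and 0.491. The call of ATG8G also ended without day 3 replicate 2 (adjusted p = 0.128) or day 5 replicate 1 (adjusted p = 0.108). From day 3 to day 4 the families TRM and IQD were shifted downward (camera adjusted p = 0.01 and 0.0374, adjusted p = 0.707 for both with an estimated correlation), and after cyclic loess the adjusted p of IQD was 0.0546.

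Of 14 sugar transporter genes of the SWEET family, 3 rose, 3 fell and 8 did not pass from day 3 to day 5, and the family as a whole was not called (camera adjusted p = 0.788). SWEET4 rose by 1.32, SWEET13 by 1.29 and SWEET1 by 0.44, though SWEET1 turned to -0.0456 when scaled to the poly-A controls, and SWEET17, SWEET10 and SWEET2 were lower (log2 changes -0.98, -0.50 and -0.44). SWEET13 rose by 1.34 from day 3 to day 4 and stood at -0.0493 from day 4 to day 5 (limma adjusted p = 0.834, and 0.00114 when scaled to the poly-A controls). The calls of SWEET1 and SWEET10 ended without day 3 replicate 1 (adjusted p = 0.0512 and 0.0782) or day 5 replicate 2 (adjusted p = 0.0758 and 0.0529), and that of SWEET2 without day 3 replicate 2 (adjusted p = 0.0628). The beta-glucosidase gene BGLU28 was lowest on day 4, at 7.33 against 8.48 on day 3 and 8.95 on day 5. Of the glutathione transferase genes, GSTU25 was up by 1.65 and GSTU20 down (log2 change -1.22) from day 3 to day 5.

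Probe sets called in both steps were counted by direction. There were 169 that rose in both steps, 127 that fell in both steps, 119 that rose and then fell and 131 that fell and then rose. Independent lists of those sizes would share 59.4, 75.2, 75.6 and 59.1. Errors of the shared day 4 arrays enter the 2 steps with opposite signs. With no effect, 50 simulations gave a mean correlation of the 2 steps' changes of -0.50 (covariance -0.00686), against -0.0014 (covariance -0.000118) as measured, across probe sets, which are not independent replicates. They gave next to no calls in both steps, which does not bear on the overlap among changed genes. The day 4 arrays are only 2 and cannot be split, so part of the 119 and 131 that turned back may come from them, whereas the 169 and 127 lie in the direction such errors work against. Leaving out 1 of these arrays changed the count from day 3 to day 4 to 1033 or 392.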
